A study of Mus musculus with 16 samples.

How the data were processed

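Stool of WT and Msc knock-out mice, healthy (time point 0) and with DSS colitis (time point 1), was profiled by 16S rRNA gene amplicon sequencing, with 16 libraries in 4 groups of 4. Per the labels, DNA was extracted with the DNeasy PowerSoil Pro kit, regions V3 and V4 were amplified with primers 341F and 805R, and libraries were read on a MiSeq. The submitters' processing notes name cutadapt without a version. The denoiser, the taxonomy classifier and its database are not stated in the sources used here.

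The deposited feature table holds read counts per sequence feature and library, whole numbers that were not rarefied, with 7 ranks of taxonomy per feature. The deposited taxonomy table gives, as a fraction, the confidence of each assignment, which lay between 0.70 and 1. Features are called ASVs here and were numbered by their total reads. All 1330 were kept. The 387 ASVs without a genus name (6.76% of reads) were summed under the next rank that has a name, so that names such as unclassified Oscillospiraceae are sums of several sequences. The 2 tables were checked to give the same genus and family for all 1330. Organelle sequences were few and stayed in the totals.

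The libraries held 49253 to 70577 reads, and 3 reads correspond to 0.00425% to 0.00609% of a library. Only 9 values in the table are single reads, and the sources used here do not say whether others were removed. Where a group had no read, a fold bound is the mean share of the other group over the share that 3 reads per library give, and it covers counting error only. Shares of single libraries have Wilson intervals at 95%.

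Reads were summed to 340 genus labels. Genera (66) and ASVs (308) with at least 5 reads in at least 4 libraries were tested with edgeR 4.0.16 in R 4.3.3. The tested ASVs held 75.6% of the reads of KO DSS replicate 1 and 82.3% of WT DSS replicate 1. In the other libraries they held 93.7% to 99.2%. All 16 libraries entered 1 quasi-likelihood fit with TMM factors, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. There were 5 comparisons: KO against WT in healthy mice and under DSS, DSS against healthy in WT and in KO mice, and the interaction, the genotype effect under DSS minus that in healthy mice. Shannon indices (natural log) were averaged over 100 draws of 49253 reads. Differences in them, in the Firmicutes to Bacteroidota ratio (log2) and in shares of phyla and families were tested with two-sided exact permutation tests, over the 70 relabellings of 4 against 4 (smallest p 0.0286) or, for interactions, 4900 relabellings within conditions. Phyla (4) and families (14) with a mean of at least 1% in any group entered as log2 of percent plus 0.01, adjusted within rank. PERMANOVA on Bray-Curtis distances was exact over the 35 splits of 4 and 4. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for these and for the figures.

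The comparisons, tests, alternatives and 19 lists of taxa were fixed before the data were examined. The 6 lists with at least 3 tested ASVs were tested with camera (limma 3.58.1, correlation preset to 0.01), and each list's summed share was tested by exact permutation. Camera asks whether a list moves more than other ASVs, fry whether its ASVs move on balance in 1 direction. Of the other lists, 8 had reads and 5 had none. Named taxa followed a rule: genera past the threshold with reads in at least 3 of 4 libraries of the higher group, up to 12 per direction by size of change, the 5 most abundant genera, genera past the threshold that belong to a list, phyla and families of at least 1%, and up to 3 ASVs per direction.

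Alternatives were TMMwsp factors, RLE factors with the poscounts rule, total counts only, DESeq2 1.42.0, limma on centred log-ratio values (pseudocount 0.5), no filter, a filter of 20 reads, only the groups compared in the fit, a replicate block, and each library left out in turn. The block was genotype with replicate number for DSS against healthy and the interaction, and replicate number alone for KO against WT. For diversity they were the inverse Simpson index, the number of ASVs, genera in place of ASVs, no rarefaction and 5000 reads. For composition they were Jaccard, Aitchison, genus-level and square-root distances. For shares they were a pseudocount of 0.1 and a minimum of 0.1%. Lists had fry and camera with an estimated correlation. Leaving out the ASVs of 1 library only was added after the data had been seen.

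The edgeR step was tested on simulated data with known changes, 10 draws per comparison. Among 66 genera it recovered, of 4-fold changes, 20% for KO against WT in healthy mice, 15% under DSS, 30% for DSS in WT and 13.3% in KO mice. Of 16-fold changes it recovered 70%, 67.5%, 70% and 70% in the same order, and of 64-fold changes 100%, 95%, 97.5% and 97.5%. Of its calls, 4.76%, 1.33%, 4.49% and 1.32% were false. Among 308 ASVs it recovered 3.18%, 3.18%, 3.64% and 3.64% of 4-fold changes, 29.5%, 37.5%, 32.5% and 31.5% of 16-fold changes and 56%, 53.5%, 53% and 56.5% of 64-fold changes, with 2.73%, 5.03%, 3.24% and 5.15% of calls false. The interaction was not simulated. Most simulated 4-fold changes were thus missed at this number of libraries.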

Results

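Stool bacteria of 16 mouse samples were profiled by sequencing variable regions V3 and V4 of the 16S rRNA gene. The samples formed 4 groups of 4 libraries: wild-type (WT) and Msc knock-out (KO) mice, each sampled healthy at time point 0 and with colitis at time point 1. Msc encodes musculin, a basic helix-loop-helix transcription factor, and the colitis was induced with dextran sulfate sodium (DSS), a polymer that damages the gut lining. The question was how loss of Msc shifts the stool microbiota in healthy mice and in mice with colitis. Healthy and DSS libraries differed in time point as well as in condition, so condition and time point cannot be told apart. No cage is given in the sources used here, so genotype and cage cannot be separated either. The labels do not say whether a replicate number stands for the same animal at both time points, and the groups were therefore compared as independent.

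The libraries held 49253 to 70577 reads, 948231 in all, spread over 1330 amplicon sequence variants (ASVs) with 340 genus labels. Of the ASVs, 883 had reads in 1 library only and 40 had reads in all 16. WT DSS replicate 1 held 844 ASVs, of which 711 were seen in no other library and carried 17.1% of its reads (the plot of diversity by group). The other 15 libraries held 172 to 280 ASVs. A genus without a read in a library may hold a share of up to 0.00425% to 0.00609% there, 3 reads of the library's total. That floor, like every fold bound given as "at least", covers counting error only, since amplified reads are not independent molecules. Where the mean of a group lay below that floor, as for Monoglobus in healthy KO mice, the Eubacterium fissicatena group in WT DSS mice and asv4 in KO DSS mice, the fitted fold change depends on the prior count. Replicates of a group spread far more than counting error, with a chi-square per degree of freedom of 28.0 to 141. Relative abundances are means over 4 libraries ± SD.

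The most abundant genus label, Muribaculaceae, took 23.2% ± 1.68 of reads in healthy WT mice, 36.3% ± 4.19 in healthy KO mice, 15.6% ± 1.32 in WT mice with DSS and 21.4% ± 2.16 in KO mice with DSS (n = 4 each). Clostridia_UCG-014, Parabacteroides, Lactobacillus and the Lachnospiraceae NK4A136 group were the next 4 in abundance. On Bray-Curtis distances between the ASV shares of the libraries, genotype accounted for 57.9% of the variation among healthy mice and 43.3% among mice with DSS. DSS against healthy accounted for 57.6% in WT and 69.3% in KO mice. Each of these 4 permutation tests on the distances gave an exact p of 0.0286, the smallest that 4 libraries against 4 allow (0.0286 after Benjamini-Hochberg adjustment). The mean distance between groups was 0.434 for KO against WT healthy, 0.416 for KO against WT under DSS, 0.467 for DSS against healthy in WT and 0.58 in KO. Within groups it was 0.264 (WT healthy), 0.25 (KO healthy), 0.285 (WT DSS) and 0.308 (KO DSS). Whether the share for DSS differed between WT and KO mice was not tested.

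**Figure D1:**
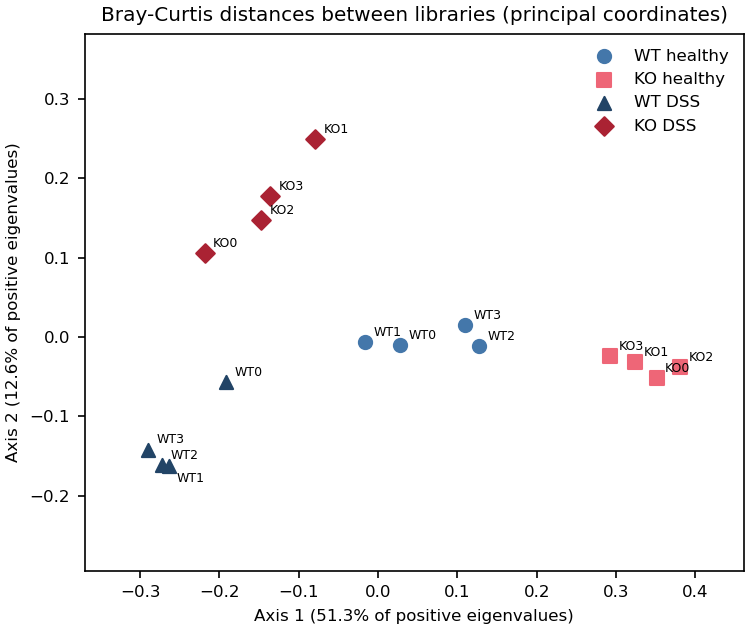
Principal coordinates of the Bray-Curtis distances between the 16 libraries, computed on ASV shares. Axis 1 carried 51.3% and axis 2 carried 12.6% of the positive eigenvalues. Points are libraries, labelled by genotype and replicate, and the 4 groups occupy separate areas.

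Diversity within libraries was compared next. The Shannon index (natural log, at an equal depth of 49253 reads) averaged 3.50 ± 0.181 in healthy WT, 3.05 ± 0.234 in healthy KO, 3.31 ± 0.419 in WT DSS and 3.28 ± 0.11 in KO DSS mice. None of the 4 comparisons passed the two-sided exact permutation test: KO minus WT was -0.45 in healthy mice (p = 0.0571) and -0.03 under DSS (p = 0.943). DSS minus healthy was -0.19 in WT (exact permutation p = 0.457) and 0.23 in KO mice (exact permutation p = 0.143). The genotype effect under DSS minus that in healthy mice was 0.42 (exact permutation p = 0.164, adjusted p = 0.273). The value for WT DSS rested on replicate 1: without it that difference of effects was 0.62 (exact permutation p = 0.00857). With the ASVs of 1 library only left out, an alternative chosen after the data had been seen, it was 0.63 (exact permutation p = 0.00735, adjusted p = 0.0367). The inverse Simpson index fell by 4.88 in healthy KO against healthy WT mice (exact permutation p = 0.0286, adjusted p = 0.0714). The number of ASVs in KO mice fell by 26.3 under DSS (exact permutation p = 0.0286, adjusted p = 0.143), the opposite sign to the Shannon index.

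**Figure D2:**
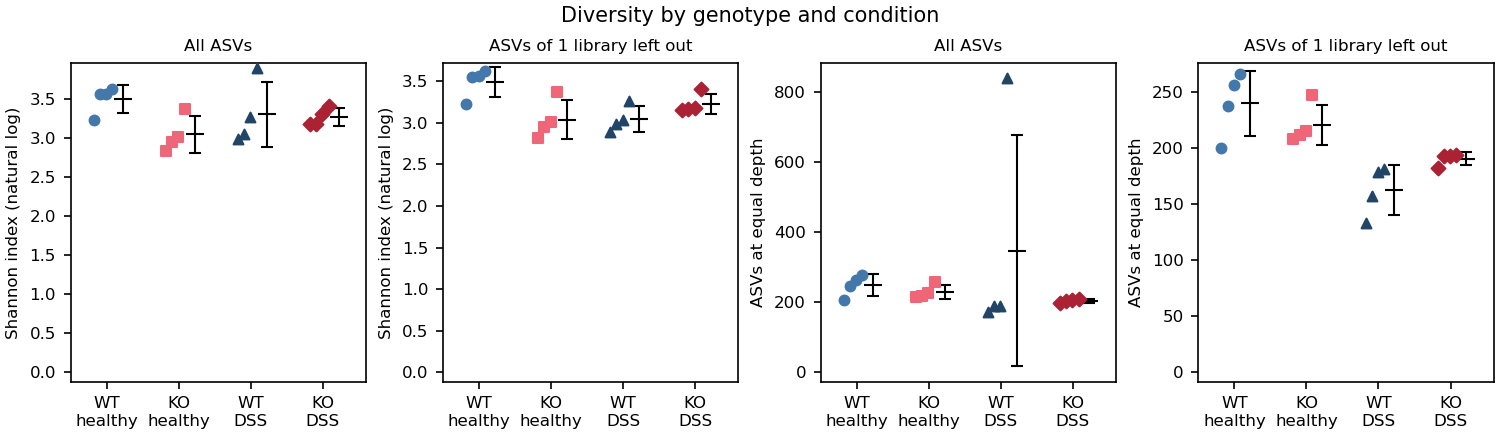
Shannon index and number of ASVs per library at equal depth, first over all ASVs and then with the ASVs seen in 1 library only left out. Points are libraries in order of value, and the black bar is the mean ± SD of 4. The library with 844 ASVs stands apart in the panel of all ASVs, and with those ASVs left out the WT DSS libraries have the lowest mean number of ASVs, 162.

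How KO differed from WT in healthy mice was asked first of genera. Ruminococcus, a genus of anaerobes that ferment plant fibre, made up 1.61% ± 0.999 of reads in healthy WT mice and had no read in any of the 4 healthy KO libraries, at least 295-fold lower (edgeR adjusted p = 6.29e-05). Monoglobus, a genus of pectin degraders, fell from 0.268% ± 0.122 to 0.00178% ± 0.00355 with reads in 1 of 4 KO libraries, a log2 fold change of -6.63 ± 1.32 (SE, adjusted p = 0.00265). Clostridia_UCG-014, an uncultured group of Clostridia, fell from 15.3% ± 4.65 to 5.35% ± 1.46 (log2 fold change -1.27 ± 0.33 SE, adjusted p = 0.0228). Muribaculaceae rose, with a log2 fold change of 0.97 ± 0.19 (SE, adjusted p = 0.00265), and all 4 KO libraries lay above all 4 WT libraries. Lactobacillus at 10.7% ± 6.14 in WT and 21.5% ± 5.66 in KO mice did not pass (log2 fold change 1.42, adjusted p = 0.208), nor did Parabacteroides (15.9% ± 2.58 and 7.35% ± 2.85, log2 -0.83, adjusted p = 0.169) or the NK4A136 group (5.21% ± 3.18 and 7.47% ± 1.21, log2 0.91, adjusted p = 0.309). Parabacteroides passed with total counts as the scale (-1.13). These were the 4 of 66 tested genera past the threshold, 1 higher and 3 lower, against 15 at an unadjusted p under 0.05, and 2 of 4 calls were higher with limma. The groups did not overlap in share for any of the 4, which is no separate test since the genera were chosen by their difference. Over all 66 tested genera the groups did not overlap for 14, where chance gives 2.86% of genera. Only Ruminococcus and Monoglobus passed without WT healthy replicate 1 or 2, when Muribaculaceae had log2 fold changes of 1.12 and 1.04, and Muribaculaceae did not pass without a filter either (0.88). Clostridia_UCG-014 did not pass without 6 of the 8 libraries in turn (log2 fold change -1.44 to -0.97 over all 8), nor in 7 other settings, among them DESeq2 (-1.05), limma (-0.57) and TMMwsp factors (-0.87).

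Single sequences were tested as well, and those of Clostridia_UCG-014 went both ways. The Ruminococcus ASV asv24 was at least 208-fold lower in healthy KO than in healthy WT mice (edgeR adjusted p = 0.000674). In Clostridia_UCG-014, asv20 was at least 359-fold lower (adjusted p = 0.0183) and asv229 at least 16.3-fold lower (adjusted p = 0.0401), while asv183 was at least 26.6-fold higher (adjusted p = 0.0209) and asv52 at least 49.1-fold higher (adjusted p = 0.0298). An unclassified Lachnospiraceae sequence, asv110, was at least 34-fold higher (adjusted p = 0.00153). Each of these 6 had reads in all 4 healthy libraries of 1 genotype and in none of the other. The WT mean of asv24 was 1.14% and 0.75% without WT healthy replicate 0, and that of asv20 was 1.96% and 0.87% without WT healthy replicate 3, so their bounds are lower without these libraries. In all, 22 of 308 tested ASVs passed, 10 higher and 12 lower, 17 of them with a group at 0, against 63 at an unadjusted p under 0.05. That count was 9, 5 and 8 without WT healthy replicates 0, 1 and 2, and 14, 3, 12 and 3 without KO healthy replicates 0, 1, 2 and 3.

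At family rank in healthy mice, Ruminococcaceae took 3.81% ± 1.02 in WT and 1.02% ± 0.429 in KO mice, and Tannerellaceae 15.9% ± 2.58 and 7.36% ± 2.85. Neither the 14 families nor the 4 phyla held a change past the threshold by the exact permutation test (4 families and 0 phyla at an unadjusted p under 0.05, lowest adjusted p 0.1). With 4 libraries against 4, a pass takes at least 9 of 14 families or 3 of 4 phyla at the smallest p of 0.0286 at once, so the lack of calls here and in the other 3 comparisons of groups says little. Of the lists of taxa fixed in advance, none of 6 passed camera (2 at an unadjusted p under 0.05, 2 past fry). The list of Ruminococcaceae and Oscillospiraceae came closest, with 5 of 81 ASVs lower and 0 higher (4 adjusted over the list alone, camera adjusted p = 0.0533, fry adjusted p = 0.00926). The Muribaculaceae list had 1 of 3 ASVs higher (2 adjusted over the list alone, camera adjusted p = 0.117, fry adjusted p = 0.0204). Lachnospiraceae had 4 ASVs higher and 2 lower of 122 (3 adjusted over the list alone, camera adjusted p = 0.598). Lactic acid bacteria had 0 of 4 past the threshold (1 adjusted over the list alone, camera adjusted p = 0.906). Erysipelotrichales had 0 of 9 (0 adjusted over the list alone, camera adjusted p = 0.955), and Enterobacterales with Enterococcus had 0 of 3 (1 adjusted over the list alone, camera adjusted p = 0.598).

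The effect of DSS in WT mice was the second question. Escherichia-Shigella, a genus of Enterobacteriaceae, rose from 0.126% ± 0.0739 to 4.85% ± 1.32 of reads, 38.5-fold, with a log2 fold change of 5.85 ± 0.81 (SE, edgeR adjusted p = 7.51e-05). Anaerostipes, a genus of butyrate producers, had no read in healthy WT mice and 3.02% ± 1.46 under DSS, at least 595-fold higher (adjusted p = 0.000181). Lachnospiraceae_UCG-001 fell from 0.33% ± 0.215 to no read in any of 4 libraries, at least 66.6-fold lower (adjusted p = 7.51e-05), and the Eubacterium xylanophilum group fell from 0.754% ± 0.702 to no read, at least 152-fold lower (adjusted p = 0.00834). Roseburia fell from 0.245% ± 0.0337 to no read, at least 49.5-fold lower (adjusted p = 0.00467). Lactobacillus fell from 10.7% ± 6.14 to 1.34% ± 0.871 (log2 fold change -2.34, adjusted p = 0.0193), and Parabacteroides rose from 15.9% ± 2.58 to 26.1% ± 4.43 (log2 1.33, adjusted p = 0.00888). In all, 15 genera passed, 7 higher and 8 lower, 6 of them with a group at 0, against 22 at an unadjusted p under 0.05. The balance depended on the setting, with 9 of 17 calls higher with TMMwsp factors, 12 of 22 with limma and 14 of 21 without a filter. The groups did not overlap for 12 of the 15, the exceptions being the Eubacterium coprostanoligenes group, the Eubacterium siraeum group and RF39, and for 21 of all 66 tested genera.

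Of the other 8 genera past the threshold in WT mice, the unclassified Lachnospiraceae fell from 6.10% ± 1.52 to 1.40% ± 0.407 (edgeR log2 fold change -1.45, adjusted p = 0.00842). Lachnospiraceae A2 fell to no read, at least 11.5-fold lower (adjusted p = 0.000245), Adlercreutzia fell by 2.65 on the log2 scale (adjusted p = 0.0172), and Marvinbryantia by 3.51 (adjusted p = 0.0323). The Eubacterium coprostanoligenes group rose 11.7-fold, from 0.172% ± 0.174 to 2.01% ± 1.31 (log2 4.19, adjusted p = 0.0239), Clostridia_vadinBB60_group by a log2 of 2.24 (adjusted p = 0.0104) and RF39 by 3.20 (adjusted p = 0.0323). The Eubacterium siraeum group was seen in 2 of 4 WT DSS libraries and in no healthy one, at least 83-fold higher (adjusted p = 0.0251), and without WT DSS replicate 0 its mean was 0.0272%, not 0.421%, and its log2 fold change of 7.66 did not pass, nor did it pass without any 1 of the 4 healthy WT libraries. Clostridia_UCG-014 (log2 0.91, adjusted p = 0.0564), the NK4A136 group (0.09, adjusted p = 0.937) and Muribaculaceae (0.03, adjusted p = 0.937) did not pass, and the sign for Muribaculaceae reversed with total counts as the scale (-0.52). Clostridia_UCG-014 passed with TMMwsp factors (1.18), with limma (1.24) and without WT healthy replicate 0 (1.22) or WT DSS replicate 1 (1.02). Parabacteroides did not pass without WT healthy replicate 1 (log2 1.22) or 2 (1.08) or WT DSS replicate 3 (1.29). Lactobacillus did not pass without WT healthy replicate 2 (-2.24) or WT DSS replicate 1 (-2.10), and RF39 did not without 6, Marvinbryantia without 5 and the coprostanoligenes group without 3 of the 8 libraries in turn. Adlercreutzia did not pass without WT healthy replicate 0 (-2.04). Without a filter Lachnospiraceae A2, Parabacteroides (1.04), Clostridia_vadinBB60_group, Adlercreutzia, Marvinbryantia and RF39 did not pass, with the replicate block Lachnospiraceae A2, Parabacteroides, the coprostanoligenes group and RF39 did not, and with only the groups compared in the fit the siraeum group did not. The healthy means of the coprostanoligenes and xylanophilum groups were 0.103% without WT healthy replicate 0 and 0.404% without WT healthy replicate 2. Without WT healthy replicate 2, 9 genera passed.

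Among single sequences in WT mice, asv18 of Anaerostipes was at least 595-fold higher under DSS, asv28 of the coprostanoligenes group at least 389-fold higher and asv41 of Clostridia_UCG-014 at least 208-fold higher. The NK4A136 sequences asv56 and asv59 were at least 110-fold and at least 97.2-fold lower, and asv33 of Clostridia_UCG-014 at least 272-fold lower. Without WT healthy replicate 3 the healthy means of asv56 and asv59 fell from 0.543% to 0.336% and from 0.481% to 0.292%. In all, 53 ASVs passed the edgeR threshold, 14 higher and 39 lower, 44 of them with a group at 0, against 109 at an unadjusted p under 0.05. Camera called 3 of 6 lists and 0 with an estimated correlation. Lachnospiraceae ASVs were lower as a set, 25 lower and 4 higher of 122 (40 adjusted over the list alone, camera adjusted p = 0.00157, adjusted p = 0.13 with an estimated correlation). Lactic acid bacteria fell from 10.7% to 1.34% of reads, 2 of 4 ASVs lower (2 adjusted over the list alone, camera adjusted p = 0.0272, adjusted p = 0.232 with an estimated correlation). Enterobacterales with Enterococcus rose from 0.14% to 4.89%, 2 of 3 ASVs higher (2 adjusted over the list alone, camera adjusted p = 0.00157, adjusted p = 0.13 with an estimated correlation). The list of Ruminococcaceae and Oscillospiraceae did not pass, with 1 ASV higher and 7 lower of 81 (6 adjusted over the list alone, camera adjusted p = 0.68), although fry called it lower (adjusted p = 0.00106), nor did Muribaculaceae or Erysipelotrichales (camera adjusted p = 0.421 each, 0 ASVs past the threshold and 0 adjusted over the list alone). By the exact permutation test 2 phyla and 5 families had an unadjusted p under 0.05, and 0 passed after an adjustment that left little room for a pass.

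The effect of DSS in KO mice was tested in the same way. Ruminococcus rose from no read to 2.32% ± 0.794, at least 425-fold higher (edgeR adjusted p = 3.84e-05), and Monoglobus from 0.00178% ± 0.00355 to 0.255% ± 0.172, a log2 fold change of 6.97 ± 1.34 (SE, adjusted p = 0.000669). The Eubacterium fissicatena group rose from no read to 1.48% ± 0.933, at least 271-fold higher (adjusted p = 0.000292), and Escherichia-Shigella from 0.188% ± 0.138 to 6.27% ± 4.53, 33.3-fold (log2 5.15 ± 0.78 SE, adjusted p = 0.000121). Lactobacillus fell from 21.5% ± 5.66 to 1.11% ± 0.961, 19.4-fold lower (log2 -4.24 ± 0.74 SE, adjusted p = 0.000299). Lachnospiraceae_UCG-001 fell to no read, at least 53.2-fold lower (adjusted p = 6.67e-05), as did Marvinbryantia, at least 33.2-fold lower (adjusted p = 0.000388), and Lachnospiraceae A2, at least 7.20-fold lower (adjusted p = 0.000279). Clostridia_UCG-014 rose from 5.35% ± 1.46 to 15% ± 3.80 (log2 1.55, adjusted p = 0.00175), Muribaculaceae fell from 36.3% to 21.4% (log2 -0.74, adjusted p = 0.00571), and Parabacteroides rose from 7.35% to 18% (log2 1.36, adjusted p = 0.00464). In all, 23 genera passed, 14 higher and 9 lower, 7 of them with a group at 0, against 30 at an unadjusted p under 0.05. The majority of higher calls did not hold with TMMwsp factors (12 of 26 higher) or limma (9 of 21). The groups did not overlap for 22 of all 66 tested genera and for 18 of the 23, the exceptions being Clostridium_sensu_stricto_1, Turicibacter, Enterococcus, the genus label Ruminococcaceae and Defluviitaleaceae_UCG-011. The NK4A136 group did not pass (7.47% ± 1.21 and 11.5% ± 9.84, log2 0.66, adjusted p = 0.323). Without KO DSS replicate 1 the DSS means of the NK4A136 group and Lactobacillus were 6.56% and 0.714%. That of Escherichia-Shigella was 4.18% without KO DSS replicate 0, and its healthy mean was 0.12% without KO healthy replicate 0.

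Of the remaining genera past the threshold in KO mice, the unclassified Oscillospiraceae rose from 0.95% ± 0.226 to 4.31% ± 1.57 (edgeR log2 fold change 2.20, adjusted p = 0.00402). The genus label Ruminococcaceae rose by a log2 of 3.61 (adjusted p = 0.00663), Harryflintia by 4.54 (adjusted p = 0.00571), Ruminococcaceae Incertae_Sedis by 2.39 (adjusted p = 0.00885), Enterococcus by 4.88 (adjusted p = 0.0194) and Defluviitaleaceae_UCG-011 by 1.69 (adjusted p = 0.0476). Parvibacter was at least 16.5-fold higher (adjusted p = 0.00175) and the Eubacterium siraeum group at least 233-fold higher (adjusted p = 0.0116), from a DSS mean of 1.27% that was 0.592% without KO DSS replicate 3, while the Parvibacter mean was 0.0596% without KO DSS replicate 1. Without 1 library the healthy means of Roseburia (0.242% for 0.782%, KO healthy replicate 3) and Clostridium_sensu_stricto_1 (0.437% for 0.735%, KO healthy replicate 2) and the DSS mean of the genus label Ruminococcaceae (1.08% for 1.63%, KO DSS replicate 2) were also lower. Roseburia fell by 6.34 on the log2 scale (adjusted p = 0.00514), Clostridium_sensu_stricto_1 by 5.01 (adjusted p = 0.00464), Adlercreutzia by 2.78 (adjusted p = 0.00663) and Turicibacter by 1.85 (adjusted p = 0.0309). Without KO DSS replicate 0, Enterococcus had a log2 fold change of 1.75, Ruminococcaceae Incertae_Sedis of 1.23 and Parabacteroides of 0.96, and none of the 3 passed. Enterococcus also failed without KO healthy replicate 2 or 3. Muribaculaceae did not pass without KO DSS replicate 2 (-0.86), Turicibacter without 5 and Defluviitaleaceae_UCG-011 without 6 of the 8 libraries in turn. With limma Clostridia_UCG-014 (1.13), Parabacteroides, Clostridium_sensu_stricto_1, the genus label Ruminococcaceae, Ruminococcaceae Incertae_Sedis, Enterococcus and Turicibacter did not pass. Without a filter Lachnospiraceae A2, Parvibacter, Muribaculaceae (-0.71), Harryflintia, Adlercreutzia, Ruminococcaceae Incertae_Sedis, Enterococcus, Turicibacter and Defluviitaleaceae_UCG-011 did not. The replicate block ended the calls of Clostridium_sensu_stricto_1, Muribaculaceae, the genus label Ruminococcaceae, Ruminococcaceae Incertae_Sedis, Turicibacter and Defluviitaleaceae_UCG-011. TMMwsp factors ended those of Ruminococcaceae Incertae_Sedis and Defluviitaleaceae_UCG-011, and fitting only the groups compared ended those of Enterococcus, Turicibacter and Defluviitaleaceae_UCG-011.

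Single sequences split further in KO mice. The Lactobacillus murinus ASV asv4 fell from 12.8% ± 6.10 to 0.00354% of reads, seen in 1 of 4 libraries (log2 fold change -11.65), and asv14 of the same species fell to no read, at least 532-fold lower (edgeR adjusted p = 8.26e-05). These 2 ASVs kept a nearly constant ratio where both had reads and are not separate results. An NK4A136 sequence, asv27, was at least 397-fold lower. Higher under DSS were asv19 of the unclassified Oscillospiraceae (at least 526-fold), asv36 of Ruminococcus (at least 241-fold) and asv32 of the fissicatena group (at least 271-fold). In all, 89 ASVs passed, 34 higher and 55 lower, 67 of them with a group at 0, against 129 at an unadjusted p under 0.05. Camera called 4 of 6 lists and 0 with an estimated correlation. The list of Ruminococcaceae and Oscillospiraceae rose from 3.59% to 13.5% of reads, 11 ASVs higher and 4 lower of 81 (10 adjusted over the list alone, camera adjusted p = 0.00813, adjusted p = 0.105 with an estimated correlation). Lactic acid bacteria fell from 21.5% to 1.11% (0.714% without KO DSS replicate 1), 3 of 4 ASVs lower (4 adjusted over the list alone, camera adjusted p = 0.00295, adjusted p = 0.105 with an estimated correlation). Lachnospiraceae had 32 ASVs lower and 11 higher of 122 (49 adjusted over the list alone, camera adjusted p = 0.00295, adjusted p = 0.105 with an estimated correlation). The summed share of the family was 15.1% in healthy and 17.7% in DSS KO mice (exact permutation p = 0.771). The DSS mean was 13.4% without KO DSS replicate 1, below the healthy mean. That share counts all ASVs, while the tested ASVs held 75.6% of the reads of KO DSS replicate 1. Enterobacterales with Enterococcus rose from 0.198% (0.125% without KO healthy replicate 0) to 6.53% (4.22% without KO DSS replicate 0), 3 of 3 ASVs higher (3 adjusted over the list alone, camera adjusted p = 0.00984, adjusted p = 0.157 with an estimated correlation). Erysipelotrichales had 1 ASV higher and 1 lower of 9 (2 adjusted over the list alone, camera adjusted p = 0.844), and Muribaculaceae 2 lower of 3 (3 adjusted over the list alone, camera adjusted p = 0.72). By the exact permutation test 0 families and 0 phyla passed after adjustment (8 and 2 at an unadjusted p under 0.05), and the lowest adjusted p was 0.05, at the limit set by the number of libraries. Without KO healthy replicate 0, 9 phyla and families passed.

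The DSS effects shared members between the genotypes. Among genera that fell, 6 were shared between the 8 of WT and the 9 of KO mice, where chance gives 1.09 (two-sided Fisher's exact p = 2.37e-05). The 6 were Lachnospiraceae_UCG-001, Lachnospiraceae A2, Roseburia, Marvinbryantia, Adlercreutzia and Lactobacillus. Among genera that rose, 3 were shared between 7 and 14 (chance 1.48, Fisher's exact p = 0.159): Escherichia-Shigella, Parabacteroides and the siraeum group. Of the ASVs that fell, 24 were shared between 39 and 55 (chance 6.96, Fisher's exact p = 3.35e-11), and of those that rose, 7 between 14 and 34 (chance 1.55, Fisher's exact p = 0.000213). These chance values take all tested taxa as independent and as able to be called in both genotypes. An ASV without a healthy read, such as asv36, cannot fall in either, and some ASVs moved together. Chance may therefore be understated and the Fisher p-values too small. Of the ASVs present in all 4 healthy and no DSS library, 15 of 26 in WT and 27 of 36 in KO mice were Lachnospiraceae.

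KO and WT mice with DSS were compared next. Anaerostipes took 3.02% ± 1.46 in WT and had no read in any of 4 KO libraries, at least 611-fold lower (edgeR adjusted p = 0.000609). The Eubacterium fissicatena group took 0.00188% ± 0.00376 in WT (reads in 1 of 4 libraries) and 1.48% ± 0.933 in KO mice, a log2 fold change of 9.16 ± 1.43 (SE, adjusted p = 0.00224). Parvibacter was seen in KO mice alone (0.0901% ± 0.0642), at least 18.2-fold higher (adjusted p = 0.00636). The unclassified Oscillospiraceae were higher in KO mice at 4.31% ± 1.57 against 0.892% ± 0.733 (log2 2.02, adjusted p = 0.0181), and so was Anaerotruncus (log2 4.09, adjusted p = 0.0181). The coprostanoligenes group was 19.3-fold lower at 0.104% ± 0.116 against 2.01% ± 1.31 (log2 -4.62, adjusted p = 0.0274). Ruminococcus was higher in KO mice, at 2.32% ± 0.794 against 0.231% ± 0.166 (log2 2.96 ± 0.88 SE, adjusted p = 0.0399), the opposite direction to healthy mice. The sequences differed, however. The ASV lost in healthy KO mice, asv24, did not pass under DSS (edgeR log2 1.31, adjusted p = 0.416), while asv36 and asv112 had reads in KO DSS mice alone. Marvinbryantia (no read in KO mice, at least 1.37-fold lower, adjusted p = 0.0399) and the xylanophilum group (adjusted p = 0.0402) made up the 9 genera past the threshold. The latter had reads in KO DSS replicate 0 alone, its log2 fold change was 0.00 without it, and it did not pass without 4 other libraries in turn. Of the 9, 6 were higher and 3 lower, 4 had a group at 0, and 20 genera had an unadjusted p under 0.05. Most calls were lower with TMMwsp factors (6 of 14 higher) and without a filter (6 of 17 higher). The groups did not overlap for 11 of all 66 tested genera and for 7 of the 9, all but Marvinbryantia and the xylanophilum group. Ruminococcus did not pass without 6 of the 8 libraries in turn (log2 2.78 to 3.26), Marvinbryantia without 6 and the coprostanoligenes group without 3, and 3 genera passed without WT DSS replicate 2. Without it the unclassified Oscillospiraceae (log2 1.84) and Anaerotruncus (4.07) did not pass. With the replicate block only Anaerostipes and the fissicatena group passed. Without a filter Parvibacter, Anaerotruncus and Marvinbryantia did not pass, with limma Marvinbryantia and the xylanophilum group did not, and with only the groups compared in the fit neither those 2 nor Ruminococcus did. Without WT DSS replicate 0 the WT mean of the unclassified Oscillospiraceae was 0.53%, and without KO DSS replicate 1 the KO means of the coprostanoligenes group and Parvibacter were 0.0483% and 0.0596%.

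In the main test the abundant genera did not pass between genotypes under DSS: the NK4A136 group at a log2 fold change of 1.48 (edgeR adjusted p = 0.0647), Parabacteroides at -0.81 (adjusted p = 0.126), Clostridia_UCG-014 at -0.63 (adjusted p = 0.179), Lactobacillus at -0.48 (adjusted p = 0.698) and Muribaculaceae at 0.20 (adjusted p = 0.539). The NK4A136 result depended on the setting: it passed with RLE factors (1.68), total counts (1.69), DESeq2 (1.68) and no filter (1.72), and without WT DSS replicate 0 (1.69) or KO DSS replicate 0 (1.66), 2 (1.71) or 3 (1.66). Its KO mean fell from 11.5% to 6.56% without KO DSS replicate 1, and its lowest log2 fold change with 1 library left out was 0.67. With TMMwsp factors Parabacteroides (-1.28) and Clostridia_UCG-014 (-1.12) passed. In share of all reads, Muribaculaceae did not overlap under DSS either, at 18.3% to 23.2% in KO and 13.9% to 17.2% in WT libraries. The shares of the other abundant genera overlapped. Single sequences passed as well, and of those named here only asv15 belongs to 1 of these abundant genera. Lower in KO mice were asv18 of Anaerostipes (at least 611-fold), asv28 of the coprostanoligenes group (at least 400-fold, adjusted p = 0.0029) and asv49 of Clostridia_vadinBB60_group (at least 162-fold, adjusted p = 0.00153). Higher were asv36 of Ruminococcus (at least 266-fold, adjusted p = 0.00162), asv15 of the NK4A136 group (at least 209-fold, adjusted p = 0.00185) and asv37 of the siraeum group (at least 257-fold, adjusted p = 0.0132), whose KO mean of 1.27% was 0.592% without KO DSS replicate 3. In all, 46 ASVs passed, 27 higher and 19 lower, 38 of them with a group at 0, against 86 at an unadjusted p under 0.05. None of the 6 lists passed camera (1 at an unadjusted p under 0.05, 2 past fry). The list of Ruminococcaceae and Oscillospiraceae had 8 ASVs higher and 1 lower of 81 (9 adjusted over the list alone, camera adjusted p = 0.169, fry adjusted p = 0.00999). Lactic acid bacteria had 1 ASV higher and 2 lower of 4 (3 adjusted over the list alone, camera adjusted p = 0.169, fry adjusted p = 0.00999), and Lachnospiraceae 10 higher and 8 lower of 122 (18 adjusted over the list alone, camera adjusted p = 0.879). The 2 lower lactic acid bacteria were asv4 and asv14 of Lactobacillus murinus, whose shares kept a nearly constant ratio. Muribaculaceae (0 of 3, 0 adjusted over the list alone, camera adjusted p = 0.879), Erysipelotrichales (1 lower of 9, 2 adjusted over the list alone, camera adjusted p = 0.72) and Enterobacterales with Enterococcus (0 of 3, 0 adjusted over the list alone, camera adjusted p = 0.961) did not pass. By the exact permutation test 6 families and 0 phyla had an unadjusted p under 0.05, and 0 passed, with the same limit of the adjustment.

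The genotype effects in healthy mice and under DSS shared no genus in the same direction (chance 0.0909 among higher and 0.136 among lower calls). The genus Ruminococcus was lower in the first and higher in the second, with different ASVs past the threshold. Of the ASVs higher in KO mice, 6 were shared between 10 healthy and 27 DSS calls (chance 0.877, two-sided Fisher's exact p = 4.30e-05). Of those lower, 2 were shared between 12 and 19 (chance 0.74, Fisher's exact p = 0.164), and 1 ASV was called in opposite directions. The limits of the chance values and Fisher p-values given for the DSS effects hold here too.

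Whether the genotype effect differed between DSS and healthy mice was tested as an interaction. For Ruminococcus, at 1.61% ± 0.999, 0%, 0.231% ± 0.166 and 2.32% ± 0.794 in WT healthy, KO healthy, WT DSS and KO DSS mice, the genotype effect differed by a log2 of 15.69 ± 1.74 (SE, edgeR adjusted p = 3.19e-05), a fitted value that depends on the prior count since 1 group had no read. For Monoglobus it differed by 6.17 ± 1.59 (SE, adjusted p = 0.042) and for the unclassified Oscillospiraceae (1.89% ± 0.715, 0.95% ± 0.226, 0.892% ± 0.733 and 4.31% ± 1.57) by 2.67 ± 0.72 (SE, adjusted p = 0.042). These 3 genera, all higher, were the calls among 66, against 11 at an unadjusted p under 0.05. That direction did not hold for all calls in other settings, since 2 of 5 were higher with TMMwsp factors, 5 of 8 with limma and 6 of 10 with DESeq2. The interaction test had no power for a taxon without a read in either healthy group. For asv36 of Ruminococcus, seen in KO DSS mice alone, it gave a log2 of 12.65 with an SE of 20625.5. Anaerostipes, Parvibacter and the fissicatena group had no healthy read either, so the lack of an interaction call for them says nothing. Muribaculaceae (log2 -0.78, adjusted p = 0.142), Lactobacillus (-1.90, adjusted p = 0.242), Clostridia_UCG-014 (0.64, adjusted p = 0.42), the NK4A136 group (0.57, adjusted p = 0.705) and Parabacteroides (0.03, adjusted p = 1) did not pass, although Muribaculaceae passed with TMMwsp factors (-1.57) and with a filter of 20 reads (-0.89). Monoglobus did not pass without 9 of the 16 libraries in turn (log2 5.73 to 9.54) nor the unclassified Oscillospiraceae without 6 (2.41 to 3.28). The latter did not pass with TMMwsp factors (2.06) or without a filter (3.09) either, and with the replicate block only Ruminococcus passed (adjusted p = 0.00839, against 0.136 for the other 2). Only 1 genus passed without WT healthy replicate 3, KO healthy replicate 1 or 3, or WT DSS replicate 1, and 5 passed without KO healthy replicate 0.

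**Figure D3:**
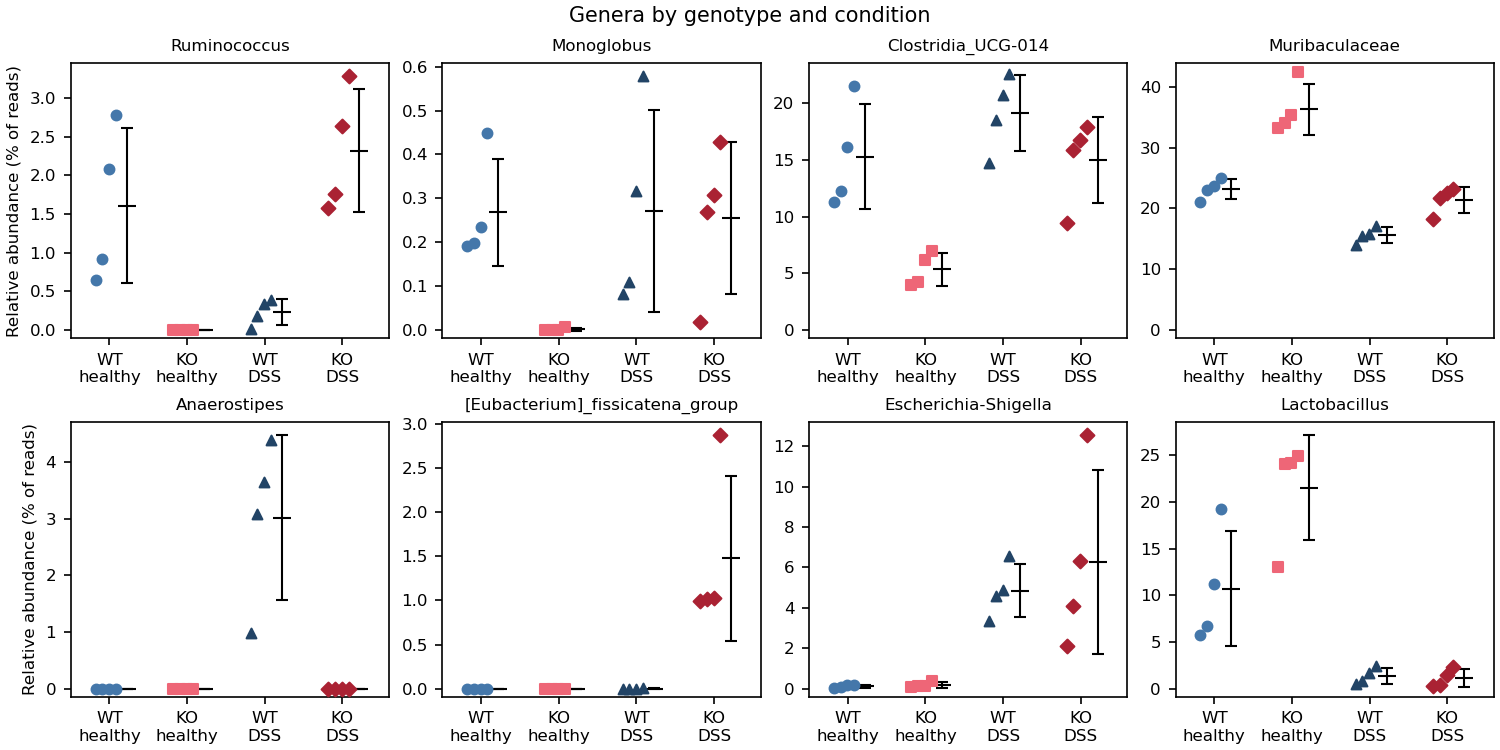
Relative abundance (% of reads) of 8 genera in the 4 groups, on linear axes from 0. Points are libraries in order of value, and the black bar is the mean ± SD of 4. Ruminococcus lies at 0 in the 4 healthy KO libraries and at 2.32% ± 0.794 in the KO DSS libraries, and Anaerostipes has reads in WT DSS mice alone.

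The choice of scaling shifted the fold changes of all genera together. The median log2 fold change over the 66 tested genera was -0.35 for KO against WT in healthy mice, 0.01 under DSS, 0.01 for DSS in WT, 0.66 for DSS in KO mice and 0.65 for the interaction. With TMMwsp factors these medians were -0.07, -0.27, 0.12, 0.09 and 0.01. Relative to the median, Muribaculaceae in healthy KO mice were at 1.32 (1.39 with TMMwsp factors) and Clostridia_UCG-014 at -0.93 (-0.80). For DSS in KO mice the relative values were 0.89 for Clostridia_UCG-014, 0.70 for Parabacteroides, -1.40 for Muribaculaceae and -4.90 for Lactobacillus. The interaction of the unclassified Oscillospiraceae was 2.03 relative to the median (2.05 with TMMwsp factors), and that of Muribaculaceae -1.42 (-1.57).

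At ASV level 17 of 308 interactions passed edgeR, 10 positive and 7 negative, against 52 at an unadjusted p under 0.05. They included asv24 of Ruminococcus (log2 13.61, adjusted p = 0.000471), asv27 of the NK4A136 group (-16.22, adjusted p = 0.000471), asv20 of Clostridia_UCG-014 (11.47), asv239 of Acetatifactor (13.93), asv78 of the NK4A136 group (-19.04) and asv155 of Clostridia_vadinBB60_group (-13.53), the last 4 at an adjusted p of 0.0468. Each of these 6 had at least 1 group without a read, so the sizes depend on the prior count. Under DSS asv78 was seen in WT DSS replicate 0 alone, and the KO DSS means of asv20 and asv239 fell from 0.176% to 0.0133% without replicate 0 and from 0.0624% to 0.0275% without replicate 3. The WT DSS mean of asv27 fell from 0.241% to 0.0944% without WT DSS replicate 0. Between 4 and 7 ASVs passed when any 1 of the 16 libraries was left out. At family rank, Ruminococcaceae took 3.81% ± 1.02, 1.02% ± 0.429, 3.29% ± 0.436 and 6.34% ± 2.03 in WT healthy, KO healthy, WT DSS and KO DSS mice. The genotype effect differed by a log2 of 2.83 (exact permutation p = 0.000408, the smallest possible, adjusted p = 0.00571). Oscillospiraceae took 4.31% ± 1.36, 2.45% ± 0.369, 3.01% ± 1.54 and 7.08% ± 2.46, a difference of 2.05 (exact permutation p = 0.00367, adjusted p = 0.0257). These 2 were the only ones of 14 families past the threshold (3 at an unadjusted p under 0.05), and 0 of 4 phyla passed (2 at an unadjusted p under 0.05). Camera called 2 of 6 lists for the interaction and 0 with an estimated correlation. The list of Ruminococcaceae and Oscillospiraceae was higher (camera adjusted p = 0.0103, adjusted p = 0.162 with an estimated correlation), and its summed share differed by a log2 of 2.24 (exact permutation p = 0.000408, adjusted p = 0.00571). Lactic acid bacteria were lower (camera adjusted p = 0.0103, adjusted p = 0.162 with an estimated correlation), and their summed share differed by -1.64 (exact permutation p = 0.12). The ASVs past the threshold were 4 of 81 and 2 of 4 (1 and 2 adjusted over the list alone). The 2 lactic acid bacteria were asv4 and asv14 of Lactobacillus murinus, whose shares kept a nearly constant ratio, so they are not separate results. Lactobacillus johnsonii (asv8) had the opposite sign and did not pass (log2 2.56, edgeR adjusted p = 0.303). The other 4 lists had camera adjusted p of 0.179 (Muribaculaceae), 0.458 (Erysipelotrichales and Enterobacterales with Enterococcus) and 0.86 (Lachnospiraceae). Of these 4, Lachnospiraceae had 4 ASVs higher and 2 lower (6 adjusted over the list alone), Erysipelotrichales 1 lower (1 adjusted over the list alone) and the others 0. The median and mean of fitted values and the camera direction differed in sign for Lachnospiraceae and Erysipelotrichales in both comparisons of KO with WT, for Muribaculaceae in both comparisons of DSS with healthy mice, and for Erysipelotrichales under DSS in KO mice, none of which passed camera.

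**Figure D4:**
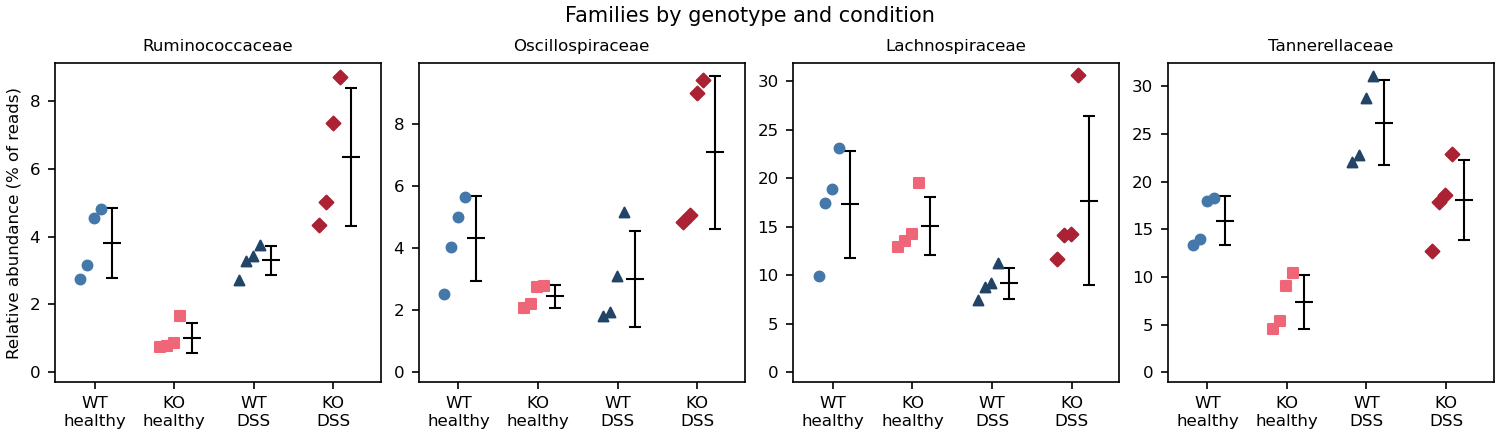
Relative abundance (% of reads) of 4 families in the 4 groups, on linear axes from 0. Points are libraries in order of value, and the black bar is the mean ± SD of 4. Ruminococcaceae and Oscillospiraceae are lowest in healthy KO mice at 1.02% ± 0.429 and 2.45% ± 0.369 and highest in KO DSS mice at 6.34% ± 2.03 and 7.08% ± 2.46.

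The Firmicutes to Bacteroidota ratio averaged 1.51 in WT healthy, 1.27 in KO healthy, 1.10 in WT DSS and 1.35 in KO DSS mice. The exact permutation p was 0.114 for KO against WT in healthy mice (adjusted p = 0.143), 0.0857 under DSS (0.143), 0.0286 for DSS against healthy in WT (0.0714) and 0.657 in KO mice (0.657). The interaction was a log2 of 0.52 (exact permutation p = 0.0106, adjusted p = 0.0531). Firmicutes took 58.6%, 55.2%, 46.3% and 52.6% in WT healthy, KO healthy, WT DSS and KO DSS mice, and Bacteroidota 39.1%, 43.7%, 42.1% and 39.4%. Proteobacteria took 0.14%, 0.192%, 5.50% ± 0.902 and 6.28% ± 4.54, nearly all of it Escherichia-Shigella under DSS in KO mice. Lists with fewer than 3 tested ASVs had no set test, and none of the 14 lists with reads had a summed share past the exact permutation test after adjustment in the 4 comparisons of groups (3, 4, 6 and 6 at an unadjusted p under 0.05, lowest adjusted p 0.133, 0.1, 0.0667 and 0.0667). A pass would have taken at least 9 of the 14 lists at the smallest p. In the same order of groups, Bacteroides with Parabacteroides took 15.9%, 7.36%, 26.1% and 18% of reads. The list named mucin degraders took 1.83% ± 1.80, 0.348% ± 0.172, 2.84% ± 4.07 and 1.46% ± 0.111. This was the share of Deferribacterota, nearly all in the Mucispirillum sequence asv10, and breakdown of mucin was not measured. The mean of that list was 0.972% without WT healthy replicate 3 and 0.812% without WT DSS replicate 0, the latter below that of KO DSS mice. Clostridiaceae with Peptostreptococcaceae took 0.198%, 0.735%, 0.0343% and 0.0227%, and bifidobacteria with Coriobacteriia 0.339%, 0.552%, 0.0384% and 0.171%. The first of these lists had a mean of 0.437% without KO healthy replicate 2 and the second 0.0192% without WT DSS replicate 0. Sutterella with Parasutterella took 0.0107% in WT DSS mice and had no read in the other groups. Sequences of mitochondria and chloroplasts took 0.00701%, 0.0009%, 0.018% and 0.0105%. Known reagent contaminants took 0.00632%, 0.00148%, 0.118% and 0.00157%, and skin and bedding bacteria took 0.0055% in KO healthy and 0.0256% in WT DSS mice with no read in the others. The WT DSS values of these last 4 lists rested on replicate 1, without which Sutterella with Parasutterella and the skin and bedding bacteria had no read, reagent contaminants took 0.00232% and mitochondria and chloroplasts 0.00406%. In KO mice reagent contaminants were seen in healthy replicate 1 alone and took 0.000945% under DSS without replicate 1, and mitochondria and chloroplasts were seen in healthy replicate 3 alone. The lists of Prevotellaceae, Rikenellaceae, sulfate reducers, Helicobacter with Campylobacter, and segmented filamentous bacteria had no read in any library.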

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

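The interaction tests of genera, ASVs, families, lists and the ratio of phyla and the test of sequencing depth in WT DSS replicate 1 were planned. The tests of the other explanations and of the splits were chosen only after the result was seen.

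WT DSS replicate 1 held 844 ASVs, far from the other 3 libraries of its group, and 711 of them had reads in no other library. At equal depth it still held 842 ASVs where the other 15 libraries held 172 to 280, which argues against deeper sequencing as the cause. The other 7 DSS libraries held a median of 199 ASVs at that depth and at most 210, against 207 to 280 in healthy libraries. These counts argue against a raised number of ASVs as a trait of the DSS condition in those 7. The 711 themselves were picked for having no read there, so their absence cannot show whether these bacteria belong to the DSS condition. Of the reads of its own ASVs, 70.6% lay in phyla listed as common in soil or sediment, but the list was drawn up after the phyla of this library had been seen, and those phyla have no read elsewhere, so DNA from soil or sediment stays open as a candidate explanation. By share of all its reads these ASVs were led by Acidobacteriota (3.80%), Proteobacteria (2.55%) and Verrucomicrobiota (2.21%), and without them the library lay at a Bray-Curtis distance of 0.21 from its 3 group mates, against 0.285 among those mates.

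Ruminococcus and Monoglobus were near 0 in healthy KO mice and not in the other 3 groups, and their genotype effects differed between DSS and healthy mice by a log2 of 15.69 and 6.17. Too few reads is argued against: at the lowest WT share, at least 97.0 reads were looked for in the smallest healthy KO library, while all 4 libraries held 0 of Ruminococcus and 4 of Monoglobus. A joint loss of several genera stays open: 1 tested genus, Ruminococcus, had no read in healthy KO and reads in all 4 healthy WT libraries, a rule that misses Monoglobus, while 11 of 66 genera had all healthy KO below all healthy WT libraries (chance gives 1.43% of genera) and 10 ASVs had reads in all 4 healthy WT and no healthy KO library. The other way round, 3 genera had all healthy KO above all healthy WT libraries. Likewise, 6 ASVs had reads in all 4 healthy KO and no healthy WT library. Both counts of genera were made on shares of all reads. On that scale the median log2 fold change over the tested genera was itself -0.70, against -0.07 with TMMwsp factors. Whether the sequences of the WT mice may have reached the KO mice between the samplings stays open as well, because 31.4% of the Ruminococcus reads in KO DSS mice lay in ASVs seen in healthy WT mice and 100% of those of Monoglobus did. Genotype is the biological explanation the design names, and it cannot be told apart from cage, which is not given and was not tested.

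The genotype effect also differed between DSS and healthy mice, by the interaction test, for the unclassified Oscillospiraceae (log2 2.67) and the families Ruminococcaceae (2.83) and Oscillospiraceae (2.05). It did for the summed share of Ruminococcaceae with Oscillospiraceae (2.24), and camera called the lactic acid bacteria (adjusted p = 0.0103, but 0.162 with an estimated correlation), whose summed share differed by -1.64 (exact permutation p = 0.12). With the replicate block the unclassified Oscillospiraceae and Monoglobus had an adjusted p of 0.136, while Ruminococcus passed (0.00839). With that block 0 families passed, at a smallest exact permutation p of 0.0286 that leaves little room for a pass. The log2 Firmicutes to Bacteroidota ratio differed by 0.52 (exact permutation p = 0.0106, adjusted p = 0.0531). Single ASVs were asv24 of Ruminococcus (13.61), asv27 of the NK4A136 group (-16.22), asv20 of Clostridia_UCG-014 (11.47), asv239 of Acetatifactor (13.93), asv78 of the NK4A136 group (-19.04) and asv155 of Clostridia_vadinBB60_group (-13.53).

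Single libraries lay far from the other 3 of their group in 25 of 161 tests, where chance gives about 1 in 20 for normally distributed values. Shares need not be normal, and a taxon with reads in 1 library of its group is always flagged. This was so for Monoglobus in KO healthy replicate 2 and the fissicatena group in WT DSS replicate 3. It was so too for the xylanophilum group in KO DSS replicate 0 and Roseburia in KO DSS replicate 1. The excess over chance is therefore not fixed. The tests share libraries and taxa and are not independent. WT DSS replicate 0 was high in Deferribacterota (8.94%), Acholeplasmataceae (3.99%), the NK4A136 group (5.95%), the unclassified Oscillospiraceae (1.98%), the siraeum group (1.60%), Defluviitaleaceae_UCG-011 (0.146%) and Adlercreutzia (0.0959%). WT DSS replicate 3 alone of its group held the fissicatena group (0.00752%). KO DSS replicate 0 was high in the fissicatena group (2.88%), Enterococcus (0.893%) and the xylanophilum group (0.239%), and KO DSS replicate 1 in Lachnospiraceae (30.7%), the NK4A136 group (26.2%) and Roseburia (0.0326%). KO healthy replicate 3 was low in Lactobacillaceae (13.1%) and high in Roseburia (2.40%) and Ruminococcaceae (1.65%). KO healthy replicate 0 was high in the coprostanoligenes group (0.123%) and in Ruminococcaceae Incertae_Sedis (0.157%), and KO healthy replicate 2 alone held Monoglobus (0.0071%). WT healthy replicate 2 was high in Firmicutes (63.3%) and the xylanophilum group (1.81%), and WT healthy replicate 0 was low in Ruminococcaceae Incertae_Sedis (0.159%) and Anaerotruncus (0%). The 95% Wilson intervals of these 24 shares were at most 0.749 percentage points wide and cover counting error only, which is less than the spread of replicates. No cause was tested for them.

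Other splits of the libraries were counted for each edgeR result. For genera the real split gave 4 calls for KO against WT in healthy mice, 9 under DSS, 15 for DSS in WT and 23 in KO mice, and it was the only 1 of 35 splits to give as many in each of the 4, the highest other being 1, 1, 0 and 3. For ASVs it gave 22, 46, 53 and 89 and was again the only 1 of 35 each time, the highest other being 1, 1, 1 and 0. For the interaction, 2 of 100 splits gave at least the 3 genera of the real one (highest other 4), and 1 of 100, the real one, gave 17 ASVs (highest other 5). For each of the 10 counts the share of splits with as many calls was under 0.05, but this does not exclude chance. With 35 splits the real one alone is a share of 0.0286, and the 10 counts overlap and were not adjusted. Splits that mix the groups also carry the group difference into the fitted spread, which lowers the calls there.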

How the results depend on the processing

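Leaving out the ASVs of 1 library only was chosen only after the result was seen, and the other tests here were planned. Of 192 values of the results that answer a comparison, under settings that keep every library, 158 kept their direction and side of the threshold or a count within 1.5 times. Of 54 calls of named genera, total counts kept 54, DESeq2, RLE factors and the filter of 20 reads 53 each, TMMwsp factors 50, limma 44, the replicate block 35, no filter 33 and the groups compared alone 43 of 51.

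Counts of genera moved for KO against WT under DSS to 14 with TMMwsp factors (9 shared) and 17 without a filter (6 shared), for DSS in KO mice to 15 without a filter (14 shared), and for the interaction to 5 with TMMwsp factors (2 shared), 10 with DESeq2 (3 shared) and 8 with limma (3 shared). Counts of ASVs moved for KO against WT in healthy mice to 38 with DESeq2 (19 shared) and 49 with limma (21 shared), for DSS in WT mice to 85 with limma (50 shared), and for the interaction to 4 with TMMwsp factors (4 shared), 42 with DESeq2 (17 shared) and 47 with limma (11 shared). Fry called 2 lists for KO against WT in healthy mice and 2 under DSS, and camera with an estimated correlation called 0 for DSS in WT, 0 for DSS in KO mice and 0 for the interaction. The inverse Simpson index had an unadjusted exact permutation p under 0.05 for KO against WT in healthy mice (-4.88, adjusted p = 0.0714) and for the interaction (5.98, adjusted p = 0.0531). For DSS in KO mice the number of ASVs reversed the sign (-26.3), and the genus index (0.34) had an unadjusted exact permutation p under 0.05. Both had an adjusted p of 0.143. With the ASVs of 1 library only left out, the Shannon interaction was 0.63. The interaction of the number of ASVs was then 47.2 (exact permutation p = 0.0351, adjusted p = 0.0439). With shares of at least 0.1%, 1 phylum or family passed for the interaction. Muribaculaceae for DSS in WT mice reversed with total counts (-0.52), where the median of all genera moved from 0.01 to -0.55. The cause was not tested for the other changes.

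With the replicate block, which leaves fewer residual degrees of freedom and takes equal numbers as related, genera numbered 2 for KO against WT under DSS (2 shared) and 1 for the interaction (1 shared). ASVs numbered 7 for KO against WT in healthy mice (6 shared), 27 for DSS in WT (26 shared), 51 in KO mice (48 shared) and 6 for the interaction (6 shared). For KO against WT equal numbers are different animals, so calls lost there do not bear on repeated sampling of 1 animal. The 4 PERMANOVA tests had R2 of 0.579, 0.433, 0.576 and 0.693 as before, at an exact p of 0.125, the smallest this design allows, and 0 families passed for the interaction. Equal replicate numbers did not mark alike libraries: their correlations ran from -0.357 to 0.233 for genera, 3 of 16 above 0.1. Those 3 were pairs of a WT with a KO library, which cannot be 1 animal. Between the time points within a genotype, where equal numbers may be 1 animal, the correlations ran from -0.267 to 0.0757.

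Without 1 library at a time, genera numbered 2 to 6 for KO against WT in healthy mice, 3 to 10 under DSS, 9 to 15 for DSS in WT, 20 to 25 in KO mice and 1 to 5 for the interaction. ASVs numbered 3 to 15, 32 to 52, 39 to 52, 68 to 79 and 4 to 7, and lists 0 to 1, 0 to 0, 2 to 3, 4 to 4 and 2 to 2. The Shannon difference ran from -0.56 to -0.38, -0.14 to 0.17, -0.39 to -0.09, 0.16 to 0.34 and 0.31 to 0.62, and the PERMANOVA R2 from 0.548 to 0.618, 0.414 to 0.524, 0.553 to 0.675 and 0.672 to 0.753. Phyla and families numbered 0, 0, 0, 0 to 9 and 2 to 3. Fewer libraries lower the power by construction, and why some counts rose was not tested. Depth limited genera below 0.00609% of a library, and at this number of libraries most simulated 4-fold changes of genera were missed, as were most 16-fold changes of ASVs (29.5% to 37.5% recovered), of which 64-fold changes were recovered at 53% to 56.5%.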

Other observations

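The tests of constant ratios were planned, and the species-level values in this part were chosen only after the result was seen.

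The genus Lactobacillus fell under DSS in both genotypes, and under DSS its species differed between the genotypes in opposite directions. Lactobacillus murinus (asv4) took 5.10% ± 3.76 in WT healthy, 12.8% ± 6.10 in KO healthy, 1.01% ± 0.596 in WT DSS and 0.00354% in KO DSS mice (n = 4 each, reads in 1 of the 4 KO DSS libraries). Under DSS it was lower in KO than in WT mice (edgeR adjusted p = 0.00153, its size not fixed since the KO mean lies below 3 reads of a library), with an interaction of a log2 of -9.78 (adjusted p = 0.00232). A second ASV of that species (asv14) had no read in KO DSS mice, at least 44.5-fold lower than in WT DSS (adjusted p = 0.000749, interaction -11.90, adjusted p = 0.000471). Where both had reads, asv4 stood at a nearly constant 4.88 times the share of asv14. With asv4 near 0 in KO DSS mice, the absence of asv14 is no separate result. Lactobacillus johnsonii (asv8) took 4.28% ± 1.5, 6.08% ± 3.82, 0.115% ± 0.156 and 1.10% ± 0.959, and under DSS it was higher in KO than in WT mice by a log2 of 3.30 ± 0.94 (SE, adjusted p = 0.0251, interaction 2.56, adjusted p = 0.303). In WT DSS mice its SD exceeded its mean. In KO DSS mice it made up nearly all of the genus, whose mean fell from 1.11% to 0.714% without KO DSS replicate 1. The Ruminococcus ASVs asv36 (1.31% ± 0.578) and asv112 (0.292% ± 0.119) were seen in KO DSS mice alone, while asv24 took 1.14% ± 0.782 in WT healthy and 0.709% ± 0.274 in KO DSS mice.

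Some abundant ASVs kept a nearly constant ratio over the libraries. Of 1613 pairs among 58 ASVs, 4 had a log2 ratio with an SD under 0.5, against a mean of 2.58 after shuffling libraries within groups. None of 100 shuffles gave more than 3, so shuffling did not reach the count, but it gave more than the tenth of the count set as the bound beforehand. That bound cannot decide on chance, because shuffling within groups keeps the group means. In healthy WT mice, for example, asv1 took 17.6% ± 1.25 and asv3 5.63% ± 0.433, which left little spread to shuffle. Chance stays open for the pairs as a set. Of these pairs 50% lay within a family, against 16.5% of all pairs, which is consistent with several 16S gene copies of 1 genome but rests on 4 pairs and leaves the question undecided. The 2 pairs within a family were asv1 with asv3 of Muribaculaceae (SD 0.0658, ratio 3.24) and asv4 with asv14 of Lactobacillus murinus (SD 0.14, ratio 4.88). The others paired asv57 of Colidextribacter with asv1 (SD 0.466) and with asv3 (SD 0.476). Since asv1 and asv3 moved together, those are not separate pairs.

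In KO DSS replicate 3, ASVs seen in no other library carried 5.03% of reads.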
